A study of Mus musculus with 8 samples.

How the data were processed

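RNA from 8 mouse macrophage cultures was sequenced, 1 library per group. Peritoneal macrophages were elicited with thioglycollate (1 ml of a 4% solution, collected 3 to 4 days later), and bone marrow-derived macrophages were grown for 5 days with 10% M-CSF. In each cell type, cells from wild-type (WT) C57BL/6 mice and from Slc6a8-/y mice, called knockout (KO) here, were left untreated or stimulated. Peritoneal macrophages received IFN-gamma at 10 ng/mL for 12 hours and bone marrow-derived macrophages IL-4 at 10 ng/mL for 6 hours. The labels give no second library for any group and do not say whether the libraries of a genotype come from different animals. No paired analysis of replicates was possible because every group holds 1 replicate.

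The authors' tables give, for each library and gene, an expected count and an FPKM value (fragments per kilobase of effective transcript length scaled to the total of fragments counted on genes). The deposited expected counts are RSEM-style estimates and were whole numbers, within 0.005, for 70.1% to 77.8% of genes. The FPKM values as deposited carry no scaling between libraries. The submitters' notes name Bowtie2 2.2.5, RSEM and the mm10 build; the RSEM version is not given in the sources used here. The tables list 16657 Entrez gene identifiers in peritoneal macrophages and 17416 in bone marrow-derived macrophages, 18125 in all. Symbols, positions and biotypes came from the GRCm38.p6 annotation for 18076 of them, 42 kept the symbol in the deposited tables, and 7 stayed without a name. A gene that a table did not list was set to 0 in that library.

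The total expected count was 10812678 to 11065427 per peritoneal library and 20553654 to 21221526 per bone marrow-derived library. A gene at about 1 FPKM had a median of 29 to 31 counts in peritoneal libraries and 48.5 to 60.0 counts in the others, so that sampling noise is large below this level. Counting error is a lower limit to the real error, because fragments copied by PCR are not independent molecules and no second library of any group shows the variation between cultures.

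Pairs of libraries were compared by the log2 ratio of FPKM plus a pseudocount of 1, over genes with a mean of at least 1 FPKM in the 4 libraries of the cell type, which left 10670 genes in peritoneal and 10906 in bone marrow-derived macrophages. The comparisons made this way were the cytokine response in each genotype, KO against WT in untreated cells, KO against WT in stimulated cells, and the KO response minus the WT response. With 1 library per group none of these has a test, and counts of genes at least 2-fold higher or lower are sizes. For each gene list the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a percentile, and given a 95% binomial interval of the median over its members, which describes spread between genes and not between cultures. The genes induced or repressed by the cytokine were those whose mean response over both genotypes was at least 2-fold.

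Additive fits, with a term for genotype and a term for the stimulus, were run for each cell type with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) on rounded expected counts in R 4.3.3. They set 2 libraries against 2 with 1 residual degree of freedom, and any interaction of genotype and stimulus adds to the residual spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SEs given with edgeR estimates were not returned by the fit. They are the absolute log2 change divided by the square root of the quasi-likelihood F statistic. They may be too small for genes with few counts in 1 condition, such as Ciita at 0.21 FPKM in both untreated peritoneal libraries. The p-values of the genotype term may be too small, since libraries of 1 genotype could share an animal. The common biological coefficient of variation was 10.4% in peritoneal and 4.6% in bone marrow-derived macrophages. A limma-trend fit (limma 3.58.1) tested the 4 KO minus WT differences of log2(FPKM + 1) against 0 over the 10073 genes measured in both cell types. The same additive fits were also run with DESeq2 1.42.0. Other computing used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

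The 38 gene lists (776 members, of which 743 matched the annotation), the comparisons, their tests and the rule for naming genes were fixed before the data were examined; most tests of explanations were chosen later. The lists cover interferon, inflammatory and IL-4 target genes, antigen presentation, JAK-STAT and SWI/SNF components, creatine handling, energy, lipid, sterol and amino acid metabolism, stress responses, the cell cycle, immediate early genes, lysosome, matrix, markers of macrophage states, B cells, T and NK cells, neutrophils, eosinophils, basophils and mast cells, dendritic cells, fibroblasts and mesothelium, and erythroid cells and megakaryocytes, sex-linked genes, X chromosome neighbours of Slc6a8, ribosomal, mitochondrial and reference genes. The rule names Slc6a8, the 8 highest and 8 lowest genes of each library pair with at least 5 FPKM in a library, up to 4 members of each list, up to 10 called genes in each direction per fit, and a panel of polarization markers. Of its 160 picks from library pairs 62 were not protein-coding, mostly small RNA genes with a median of 6.5 counts. The rule was therefore applied a second time to protein-coding genes, a choice made after seeing the data. Near-identical gene copies such as Tmem254b and Tmem254c, Rps27rt, Rpl37rt, H3c14 and H3c15, Fam177a and Fam177a2, Hba-a1 and Hba-a2, and Pnp2 are uncertain because short reads cannot be told apart between copies.

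The tests were tried on simulated data made from these libraries. With 100 genes changed by a log2 of 1, the edgeR fits called 95 to 98 of them and made 0 to 15 false calls among 12019 to 12835 genes. With a log2 of 3 they called 100 of 100. The limma fit of 4 pairs called 100 of 100 at either size with 13 false calls. These simulations gave all genes the same spread and held no interaction of genotype and stimulus. The edgeR changes were planted in well-counted genes only. The shares called therefore do not carry over to genes with few counts or to genes whose cytokine response differs between genotypes. Among library pairs, 200 of 200 genes changed by a log2 of 3 passed 2-fold with 0 unchanged genes doing so. That simulation used a small fixed noise without counting error and changed well-expressed genes only. Its 0 therefore says nothing about genes with few counts. Of 200 unchanged lists, 94.5% and 95.5% fell in the middle 95% of random lists. These lists were random draws of independent genes, ranked among other such draws. A share near 95% thus follows by construction and does not show how lists of co-regulated genes behave.

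Alternatives tried were pseudocounts of 0.1 and 5, no expression filter or a mean of at least 5 FPKM, rescaling of each library by the median of its gene ratios, a 1.5-fold limit, the DESeq2 fit, DESeq2 size factors in edgeR, no filter on low counts, a 4-fold choice of responding genes, and leaving out each KO and WT pair. A limma-trend additive fit on log2(FPKM + 1) and the restriction to protein-coding genes were added after seeing the data. Mitochondrially encoded transcripts had no measured member, so that list has no value. Raw reads were not used here.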

Results

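The data are 8 RNA sequencing libraries, 1 for each combination of cell type, genotype and treatment. Peritoneal macrophages of WT and KO mice were untreated or given IFN-gamma, the cytokine of classical activation. Bone marrow-derived macrophages of the same genotypes were untreated or given IL-4, the cytokine of alternative activation. The KO mice lack Slc6a8, the X-linked creatine transporter, and the series asks how macrophages without creatine uptake change their transcriptome during polarization. Total expected counts per library were 10812678 (WT untreated), 11065427 (WT IFN-gamma), 10940358 (KO untreated) and 10986660 (KO IFN-gamma) in peritoneal macrophages. In bone marrow-derived macrophages they were 21148299 (WT untreated), 20553654 (WT IL-4), 21163660 (KO untreated) and 21221526 (KO IL-4). There is no replicate of any group, so no level, library-pair ratio or list median below carries an error between cultures. Differences between 2 libraries are sizes without a test. The SEs and adjusted p-values below come from fits across groups or across KO and WT pairs. Their error rests on the spread left between libraries of different groups, or between such pairs, and not between replicates. The edgeR SEs are derived from the F statistic and may be too small for genes with few counts in 1 condition. "Rose" and "fell" are used of genes called in the additive fits.

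Slc6a8 (chromosome X, 73673133 to 73682502 on GRCm38) was near absent from all 4 KO libraries. In peritoneal macrophages it stood at 163.54 FPKM in untreated and 39.52 FPKM in IFN-gamma-treated WT cells, against 0.73 and 0.18 FPKM in KO cells. In bone marrow-derived macrophages it stood at 97.34 and 87.92 FPKM in untreated and IL-4-treated WT cells, against 1.71 and 1.15 FPKM in KO cells. The edgeR genotype term put the log2 change at -7.81 (SE 0.15, adjusted p = 5.21e-05) in peritoneal and -6.02 (SE 0.09, adjusted p = 6.4e-10) in bone marrow-derived macrophages. IFN-gamma lowered it as well: the edgeR stimulus term in peritoneal macrophages was -1.97 (adjusted p = 0.000202).

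**Figure D1:**
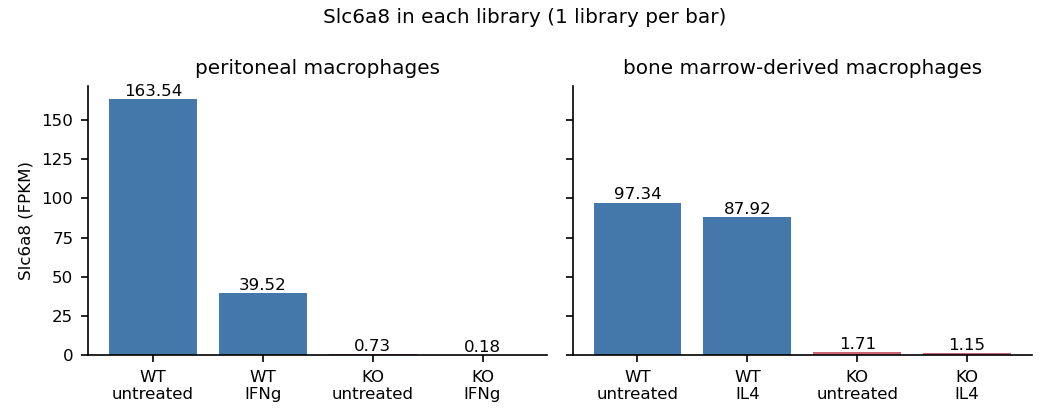
Slc6a8 level (y axis, FPKM from 0) in each of the 8 libraries, 1 library per bar, with WT in blue and KO in red. The 4 KO libraries lie between 0.18 and 1.71 FPKM and the 4 WT libraries between 39.52 and 163.54 FPKM.

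IFN-gamma changed the peritoneal macrophages deeply in both genotypes. The chemokine gene Cxcl9 went from 0.39 to 190.57 FPKM in WT and from 1.67 to 936.76 FPKM in KO cells, and Ciita, the master regulator of MHC class II genes, from 0.21 to 58.94 and from 0.21 to 61.64 FPKM. Irf1, a transcription factor of the interferon response, went from 12.73 to 580.16 FPKM in WT and from 13.06 to 660.46 FPKM in KO cells, and the guanylate-binding protein gene Gbp2 from 6.53 to 3400.1 and from 13 to 3428.48 FPKM. Mmp12, the macrophage elastase, dropped from 1039.05 to 90.25 FPKM in WT and from 1687.94 to 141.16 FPKM in KO cells, and Ckb, the cytosolic creatine kinase, from 103.56 to 10.54 and from 135.88 to 11.68 FPKM. Cd14, the co-receptor for lipopolysaccharide, stood at 104.98 and 134.31 FPKM before and 15.88 and 18.18 FPKM after IFN-gamma.

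Over both genotypes, edgeR called 2077 genes that rose and 1796 that fell with IFN-gamma among 12052 tested. DESeq2 called 1272 and 877. The estimates were 9.20 for Cxcl9 (SE 0.15, adjusted p = 7.74e-06), 8.27 for Ciita (SE 0.15, adjusted p = 7.74e-06) and -3.46 for Mmp12 (SE 0.10, adjusted p = 1.23e-05). Serpina3g, Serpina3f, Calhm6, Gbp3, Ifi47, Acod1, Ralgds and Cxcl10 followed among the genes that rose, and Rhov, Ckb, Cdkn1c, Rnf128, C5ar1, Arhgap22, Prokr1, Sel1l3 and Cd14 among those that fell. Nos2, the inducible nitric oxide synthase, Cd274 (PD-L1) and Tnf also rose, by 9.41, 3.97 and 4.64 on the log2 scale. Of the marker panel, Ido1, Il6, Il1b and Il12b averaged 0.16, 0.11, 0.09 and 0.63 FPKM over the 4 libraries, below the level compared.

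The interferon and antigen presentation lists moved as blocks. Counts are given over all genes, with the count adjusted over the list alone in parentheses. Among MHC class I and immunoproteasome genes such as Tap1 and B2m 17 of 17 rose (17), and among type I interferon response genes such as Ifit2 and Isg15 26 of 28 (27). Of the 11 MHC class II presentation genes 9 rose (10), among them H2-Aa and Cd74, and the protease gene Lgmn was the 1 that fell (1). The inflammatory and NF-kB list had 16 members up (18), such as Ptgs2 and Tnf, and 3 down (3), Ccl3, Il1a and Il18. On this list DESeq2 called 13 up and 0 down, and limma 15 up and 3 down. Among JAK-STAT receptors, kinases and regulators 15 of 22 rose (15), including Socs1, Socs3 and Jak2.

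Metabolic lists moved in parts. Genes of the ATF4 amino acid stress response, such as Asns and Slc7a5, rose in 18 of 22 cases (18) and fell in 1 (1). Fatty acid oxidation and lipid uptake genes fell in 13 of 25 cases (17) and rose in 2 (2); Plin2, which coats lipid droplets, stood at 1020.19 FPKM before and 141.3 FPKM after IFN-gamma in WT cells. In the creatine list Gatm, the first enzyme of creatine synthesis, rose, while Ckb, Slc6a8 and Gamt fell (1 up and 3 down). Arginine, polyamine and proline metabolism had 8 up (8) and 3 down (3) of 17, oxidative phosphorylation 10 of 34 up (10), glycolysis 4 up (4) and 1 down (1) of 20, and the tricarboxylic acid cycle and itaconate list 5 up (5) and 1 down (1) of 22, with Acod1 in front. DESeq2 called 3 oxidative phosphorylation genes up, and 1 tricarboxylic acid cycle gene up and 1 down. Cholesterol synthesis had 2 up (2) and 2 down (2) of 23.

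Among the other functional lists, IL-4 and STAT6 targets had 15 up (16) and 6 down (6) of 29, with Pparg and Mrc1 among those that fell. The unfolded protein response and heat shock list had 6 up (9) and 3 down (3) of 17, HIF targets 6 up (7) and 1 down (1) of 16, NRF2 targets 2 up (2) and 3 down (3) of 13, and immediate early genes 8 up (8) and 5 down (6) of 18. The lysosome and phagocytosis list had 7 up (9) and 11 down (11) of 26, and the extracellular matrix and tissue repair list 8 up (8) and 10 down (11) of 24. The cell cycle list had 2 up (1) and 2 down (2) of 30, and SWI/SNF subunits 1 up (1) and 2 down (2) of 18. Each count is adjusted over all genes and, in parentheses, adjusted over the list alone.

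Without a test, 634 genes were at least 2-fold higher and 487 at least 2-fold lower after IFN-gamma in WT cells, and 776 and 704 in KO cells. Of these 553 were higher and 406 lower in both genotypes, where unrelated lists would share 46.11 and 32.13. Across the 10670 genes, which are not independent replicates, the responses of the genotypes had a Spearman rho of 0.807 and a Pearson r of 0.891. Rescaling each library by the median of its gene ratios shifts the median of all genes by 0.128 in the KO response and 0.061 in the WT response.

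**Figure D2:**
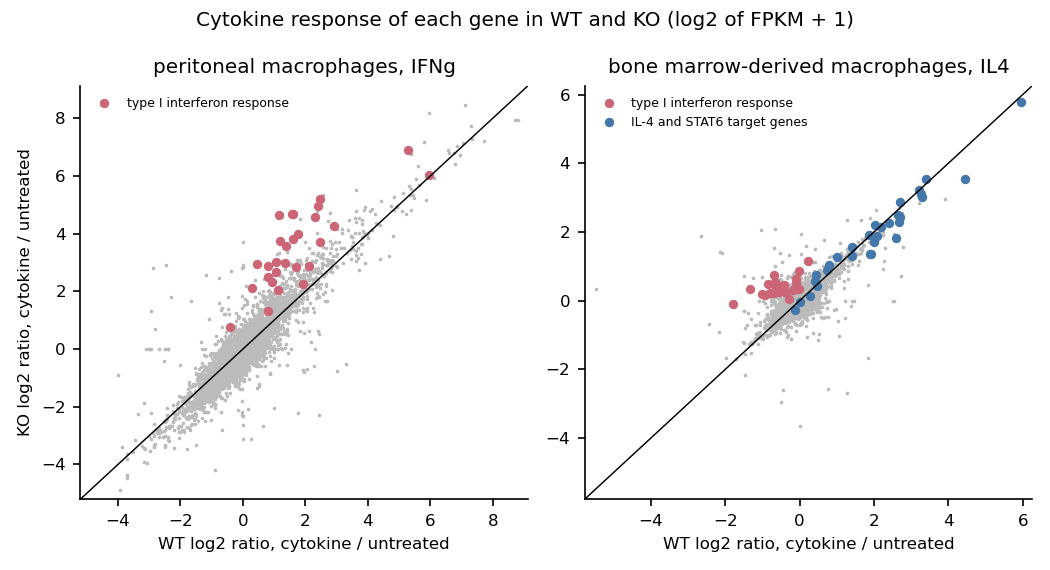
Log2 ratio of FPKM + 1 between the cytokine-treated and the untreated library in WT (x axis) and KO cells (y axis), 1 point per gene, for IFN-gamma in peritoneal (left) and IL-4 in bone marrow-derived macrophages (right), with the line of equal response in black. Type I interferon response genes (red) lie above the line, with a list median of the KO minus WT response of 1.76 on the left and 0.91 on the right, while IL-4 target genes (blue, right) lie close to it, at -0.13.

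Untreated KO and WT peritoneal macrophages differed in few genes, and the complement genes C1qa, C1qb and C1qc stood out among those that were lower in KO. C1qc was at 206.62 FPKM in WT and 77.53 FPKM in KO cells, C1qb at 273.31 and 104.44 FPKM, and C1qa at 68.26 and 29.07 FPKM. Cd5l, a secreted macrophage protein, was at 7.54 and 2.02 FPKM. On the higher side were Slc6a12, a betaine and GABA transporter of the same family as Slc6a8 (7.63 FPKM in WT, 31.64 in KO), the organic anion transporter Slco4a1 (14.75 and 35.05) and the interferon-induced gene Isg15 (2.6 and 6.35).

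In total 38 genes were at least 2-fold higher and 45 at least 2-fold lower in untreated KO cells, of which 16 and 14 were protein-coding. Among gene lists, cholesterol synthesis genes had a median log2 ratio of -0.29 (95% interval -0.35 to -0.15, percentile 0 among random lists) with 20 of 23 members below 0, and MHC class II genes a median of -0.40 (-0.74 to 0.00). MHC class I genes had a median of -0.21 (-0.26 to -0.07), and cytosolic ribosomal protein genes one of -0.21 (-0.26 to -0.20) with 35 of 35 below 0. Type I interferon genes stood at 0.08 (0.04 to 0.17). In the IFN-gamma pair, the cholesterol synthesis median was -0.02 (percentile 50.74). The MHC class II median there was -0.17 (percentile 19.63), the MHC class I median -0.02 (percentile 85.22) and the ribosomal median -0.23. Over all genes, the edgeR genotype term in peritoneal macrophages called 0 members of the cholesterol, MHC class II, MHC class I and ribosomal lists.

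After IFN-gamma, type I interferon response genes, the antiviral set that type I interferons induce, were higher in KO than in WT cells with a median log2 ratio of 2.05 (95% interval 1.61 to 2.36, percentile 100), and 24 of 28 were at least 2-fold higher. Oasl1 was at 6.43 FPKM in WT and 65.53 FPKM in KO cells, Ifit3 at 2.64 and 30.24 FPKM, Rsad2 at 5.36 and 48.41 FPKM, Ifit1 at 6.55 and 50.74 FPKM and Usp18 at 9.39 and 66.32 FPKM. The chemokine gene Ccl5 (10.97 and 86.48 FPKM) and Nos2 (75.17 and 476.97 FPKM) were among the 8 highest protein-coding genes as well, besides Ifi208. Besides Slc6a8, genes far lower in KO cells were Tgfbi (7.97 FPKM in WT, 0.75 in KO), Pld4 (70.52 and 18.58), the complement receptor C3ar1 (43.79 and 11.93), Kctd12 and Adssl1.

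In all 166 genes were at least 2-fold higher and 95 at least 2-fold lower in KO cells after IFN-gamma (132 and 69 of them protein-coding), but with a 1.5-fold limit fewer were higher (432) than lower (475). With the untreated pair they shared 10 higher genes, where unrelated lists would share 0.59, among them Isg15, Slc6a12 and Slco4a1, and 12 lower genes against 0.40, among them C1qc and Gdf15; many of the others are small RNA genes. Another 5 genes were higher untreated and lower after IFN-gamma, and 6 the reverse. No number for unrelated lists was computed for these opposite overlaps, but both also lie above 0.59 and 0.40. An excess over unrelated lists therefore does not by itself show that the pairs agree. Inflammatory and NF-kB genes had a median of 0.67 (0.27 to 1.04). Unfolded protein response genes stood at -0.51 (-0.79 to 0.00); Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, was at 61.94 FPKM in WT and 27.57 FPKM in KO cells. Macrophage identity markers had a median of -0.40 (-0.92 to 0.05), with Csf1r, the M-CSF receptor, at 118.3 and 65.4 FPKM. Fibroblast and mesothelial markers moved the same way, with a median of -0.52 (-0.85 to -0.11), and the matrix list stood at -0.31 (-0.54 to 0.44).

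Set against each other, the KO response to IFN-gamma exceeded the WT response by a median of 1.76 on the log2 scale (1.32 to 2.24) over the type I interferon genes, 23 of which differed at least 2-fold. The WT response of this list was 1.47 (1.07 to 1.91) and the KO response 3.30 (2.86 to 4.26). Among the largest excesses were those of Oasl1 (3.49), Mx1 (3.11), Ifit3 (3.07), Ccl5 (2.77), Ifit1 (2.71), Ifi208 (2.68) and Irf7 (2.58). Pnp2, Fam177a and H3c14 had values of this size too and are uncertain near-identical copies. Ccr1 (-1.95), Tgfbi (-1.92) and Tlr13 (-1.82) were at the other end. The inflammatory list exceeded by 0.68 (0.52 to 0.95) and the unfolded protein response list fell short by a median of -0.43 (-0.76 to -0.14).

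Across all 680 genes induced at least 2-fold on average, the KO response minus the WT response had a median of 0.288 (0.23 to 0.33), with 507 above 0. The 562 repressed genes had a median of -0.271 (-0.31 to -0.24), with 448 below 0, while all genes had -0.063. Without the type I interferon list the 653 other induced genes had a median of 0.262. In all 161 genes had a KO minus WT response of at least 2-fold and 89 one as far below, against 438 and 475 with a 1.5-fold limit. No test of this difference was possible with 4 libraries and 4 groups.

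**Figure D3:**
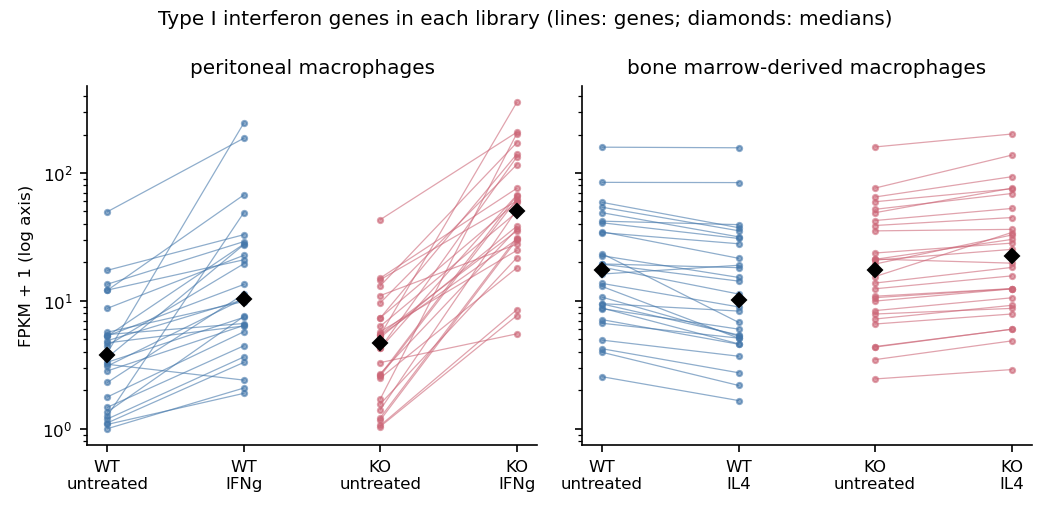
Level of the 28 type I interferon response genes (y axis, FPKM + 1 on a log axis) in each library, with lines joining the untreated and the cytokine-treated library of WT (blue) and KO cells (red), and list medians as diamonds, for peritoneal (left) and bone marrow-derived macrophages (right). The median log2 response to IFN-gamma was 1.47 in WT and 3.30 in KO cells, and that to IL-4 was -0.61 and 0.33.

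Over both treatments, the edgeR genotype term in peritoneal macrophages called 3 genes that rose in KO cells and 1 that fell. Cxcl9 rose by 2.28 (SE 0.12, adjusted p = 0.0123), Nos2 by 2.58 (SE 0.19, adjusted p = 0.0493) and Ifit2, an antiviral gene, by 2.02 (SE 0.16, adjusted p = 0.0493); Slc6a8 fell. All 3 were higher in KO in both the untreated and the IFN-gamma pair, but their untreated levels were low. Untreated WT and KO cells had 0.39 and 1.67 FPKM of Cxcl9, 0.22 and 0.64 of Nos2, and 0.26 and 0.71 of Ifit2. A fit with 1 residual degree of freedom favours genes whose pairs agree, so the agreement adds no support to the calls. DESeq2 called 19 higher and 21 lower genes, including Slc6a12 (2.43, adjusted p = 2.72e-08), C1qc (-1.24, adjusted p = 5.41e-08), C1qb (-1.17, adjusted p = 1.46e-06) and C1qa (-1.08, adjusted p = 4.04e-05), which edgeR left at an adjusted p of 0.0766, 0.0766, 0.0895 and 0.0841. With limma on log2(FPKM + 1) no gene was called, against 1277 at an unadjusted p under 0.05 (1680 in edgeR), and Nos2 and Ifit2 lost their call among protein-coding genes alone. These p-values may be too small if libraries of a genotype share an animal.

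By list, edgeR called Ifit2 among 28 type I interferon genes (20 up adjusted over the list alone), Nos2 among 17 arginine genes (1 up and 1 down adjusted over the list alone) and Slc6a8 in the creatine list (1 down adjusted over the list alone). On the 33 tested lists without a call, 536 genes, it called 0, with 138 at an unadjusted p under 0.05, 9 by DESeq2 and 0 by limma. Adjusted over the list alone, edgeR called 5 inflammatory genes up, 4 IL-4 targets up and 2 down, 4 MHC class II genes down, 6 macrophage identity genes down, 1 matrix gene up and 6 down, 3 unfolded protein response genes down, and 2 each of the fatty acid, HIF and immediate early lists down. It also called, adjusted over the list alone, 2 T and NK cell markers, 1 tricarboxylic acid cycle gene and 1 eosinophil, basophil or mast cell marker up, and 1 each of the ATF4, resident macrophage, dendritic cell and fibroblast lists down.

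IL-4 turned on its known programme in bone marrow-derived macrophages of both genotypes. Arg1, which splits arginine into ornithine and urea, went from 1.28 to 139.89 FPKM in WT and from 0.42 to 76.97 FPKM in KO cells. Mrc1, the mannose receptor CD206, went from 28.07 to 266.33 and from 22.19 to 214.94 FPKM, the transcription factor Egr2 from 6.34 to 47.03 and from 4.18 to 36.49 FPKM, and Socs1, a feedback inhibitor of cytokine signalling, from 1.22 to 20.86 and from 1.54 to 19.72 FPKM. Retnla was listed at 0 in both untreated libraries and reached 20.97 FPKM in WT and 10.65 FPKM in KO cells. Gatm, the first enzyme of creatine synthesis, went from 32.6 to 214.73 FPKM in WT and from 36.97 to 243.71 FPKM in KO cells. The fractalkine receptor Cx3cr1 dropped from 74.99 to 18.38 FPKM in WT and from 78.32 to 23.69 FPKM in KO cells.

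Over both genotypes edgeR called 1542 genes that rose and 1189 that fell with IL-4 among 12879 tested. DESeq2 called 672 and 416. The estimates were 3.30 for Mrc1 (SE 0.05, adjusted p = 3.03e-10), 7.04 for Arg1 (SE 0.11, adjusted p = 3.03e-10), 2.76 for Gatm (SE 0.05, adjusted p = 6.29e-10) and -1.83 for Cx3cr1 (SE 0.07, adjusted p = 1.1e-07). Flt1, Slc7a2, Egr2, Clec7a, Ptgs1, Gda and Fyn followed among those that rose, and Clec4d, Cd14, Tlr2, Abca1, Cd93, Itga4, Pid1, Itga6 and Cgnl1 among those that fell. Chil3, Irf4, Pdcd1lg2, Mgl2 and Cish rose too, to 7.8, 7.6, 2.79, 5.92 and 3.66 FPKM in WT cells. Ccl17, Ccl22 and Ccl24 averaged 0.04, 0.42 and 0.53 FPKM over the 4 libraries.

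By list, with the count adjusted over the list alone in parentheses, IL-4 and STAT6 targets rose in 29 of 33 cases (30, and 1 down). MHC class II genes rose in 9 of 13 (9), among them Cd74 and Ciita, and MHC class I genes rose in 8 (12) and fell in 1 (1) of 17, with 2 up by DESeq2. Oxidative phosphorylation genes rose in 21 of 34 (24), such as Atp5b and Uqcrc1, although DESeq2 called 4, and tricarboxylic acid cycle genes rose in 9 (11) and fell in 1 (1) of 22, of which DESeq2 called 0 and limma 4 up and 1 down. Fatty acid genes rose in 8 (10) and fell in 2 (2) of 25, arginine genes rose in 8 of 17 (8), and in the creatine list Gatm rose (1) and Ckb fell (1). NRF2 targets fell in 7 of 14 (8), among them Hmox1, the heme oxygenase gene. The inflammatory list had 3 up (4) and 6 down (8) of 20, Tnf and Nlrp3 among those that fell.

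Other lists moved in smaller parts with IL-4, counted the same way, over all genes and, in parentheses, adjusted over the list alone. JAK-STAT components had 7 up (7) and 1 down (1) of 23, and SWI/SNF subunits 1 up (1) and 1 down (1) of 18. Glycolysis had 3 up (4) and 4 down (4) of 20, cholesterol synthesis 5 of 23 up (6), none of them by DESeq2 or limma, the ATF4 list 8 of 22 up (9, and 1 down), the unfolded protein response list 5 of 17 up (7), and HIF targets 2 up (2) and 2 down (2) of 17. On the ATF4 list DESeq2 called 3 up, and limma 5 up and 1 down. On the unfolded protein response list each called 1 up. The cell cycle list had 1 up (1) and 1 down (1) of 30, immediate early genes 9 up (9) and 4 down (5) of 20, the lysosome list 6 up (6) and 5 down (7) of 25, and the matrix list 7 up (7) and 6 down (8) of 25. Of 28 type I interferon genes Zbp1 and Irf7 rose over all genes, while adjusted over the list alone edgeR called 0, against 4 higher and 1 lower at an unadjusted p under 0.05, and DESeq2 and limma called 0.

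Without a test, IL-4 left 139 genes at least 2-fold higher and 49 at least 2-fold lower in WT cells and 138 and 37 in KO cells, with 107 and 19 in both where unrelated lists would share 1.76 and 0.17. The Spearman rho of the responses across 10906 genes was 0.634 and the Pearson r 0.726.

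Genes of the extracellular matrix were lower in KO than in WT bone marrow-derived macrophages, both untreated and after IL-4. Col1a1, a chain of type I collagen, was at 208.73 and 198.89 FPKM in untreated and IL-4-treated WT cells and at 109.59 and 93.66 FPKM in KO cells. Col6a1 was at 33.27 and 35.19 FPKM in WT and 15.05 and 15.27 FPKM in KO cells, Col3a1 at 33.65 and 29.45 against 15.92 and 13.04, and the protease inhibitor Timp3 at 50.93 and 40.84 against 24.0 and 19.46. Gdf3, a TGF-beta family gene, stood at 12.29 and 11.86 FPKM in WT and 3.9 and 3.64 FPKM in KO cells. Ide, the insulin-degrading enzyme, was higher in KO, at 12.52 and 12.12 FPKM in WT and 21.82 and 21.92 FPKM in KO cells.

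The edgeR genotype term called 195 genes that rose and 474 that fell in KO bone marrow-derived macrophages among 12879. DESeq2 called 44 and 126 and limma on log2(FPKM + 1) 63 and 182. Col6a1 fell by 1.17 (SE 0.05, adjusted p = 7.73e-06), Timp3 by 1.08 (SE 0.05, adjusted p = 7.73e-06), Col3a1 by 1.12 (SE 0.05, adjusted p = 8.53e-06) and Col1a1 by 1.01 (SE 0.05, adjusted p = 1.07e-05); Col6a2 and Col1a2 fell as well. Ide rose by 0.83 (SE 0.05, adjusted p = 2.52e-05), followed by Lsp1, Slc2a6, L1cam, Vwf, Itgal, Hmga2 and Atp2a3, all by 0.45 to 0.59. Tmem254b (-6.39, adjusted p = 1.07e-05), Tmem254c (4.59, adjusted p = 0.000388) and Gm2026 were called too and are uncertain near-identical copies; Tmem254b was at 15.54 and 12.77 FPKM in WT and 0.32 and 0 FPKM in KO cells, and Tmem254c at 0 and 1.58 against 17.5 and 15.64 FPKM. These p-values may be too small if the 2 libraries of a genotype share an animal.

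Among the lists, given with the count adjusted over the list alone in parentheses, 12 of 25 matrix genes fell (15, and 2 up) and 6 of 8 fibroblast and mesothelial markers (8), with Col1a1, Col1a2 and Col3a1 on both lists. Cholesterol synthesis genes fell in 8 of 23 cases (14), with Sqle at 25.22 FPKM in untreated WT and 18.7 FPKM in untreated KO cells, and DESeq2 called 2 of them. Of the IL-4 and STAT6 targets 8 of 33 fell (11), among them Arg1 by 0.90, Retnla, Mrc1 by 0.32, Egr2, Myc and Fn1, while Flt1 and Klf4 rose (3). DESeq2 called 4 of these targets down and limma 5, and both called 0 up. MHC class I genes rose in 5 of 17 cases (10, and 1 down), Psmb8 and Tap2 among them, although DESeq2 called 1 and limma 0. Oas1a was the 1 type I interferon gene of 28 that rose over all genes (21), and neither DESeq2 nor limma called it. C1qa fell by 0.43 (adjusted p = 0.000364), C1qc and Maf fell and Mpeg1 rose in the macrophage identity list of 21 (5 up and 4 down).

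Smaller parts of other lists were called for genotype, again with the count adjusted over the list alone in parentheses, and several of these calls depend on the tool. Down were 4 of 22 ATF4 genes (8, and 1 up; DESeq2 called 0 and limma 2), 3 of 30 cell cycle genes (11, and 1 up; DESeq2 and limma called 0), 3 of 17 HIF targets (3, and 1 up; DESeq2 called 0 and limma 2), 1 of 14 NRF2 targets (2, and 1 up), 1 of 17 unfolded protein response genes (2), 1 of 25 fatty acid genes (1), 1 of 20 inflammatory genes, Csf1 (1, and 2 up), and Slc6a8 of the creatine list (1, and 2 up). Immediate early genes had 1 up (2) and 5 down (7) of 20, Egr1 among the latter, the lysosome list 1 up (2) and 3 down (3) of 25, the arginine list 1 up (3) and 2 down (7) of 17, of which DESeq2 called 0 and limma 1 down, and glycolysis 1 up (1) and 1 down (1) of 20. Acod1 in the tricarboxylic acid cycle list (1) and Ctss in the MHC class II list (1) rose. The 7 lists without a call, JAK-STAT, SWI/SNF, oxidative phosphorylation, ribosomal, sex-linked, neutrophil and dendritic, hold 127 genes, with 7 at an unadjusted p under 0.05, and DESeq2 and limma called 0.

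**Figure D4:**
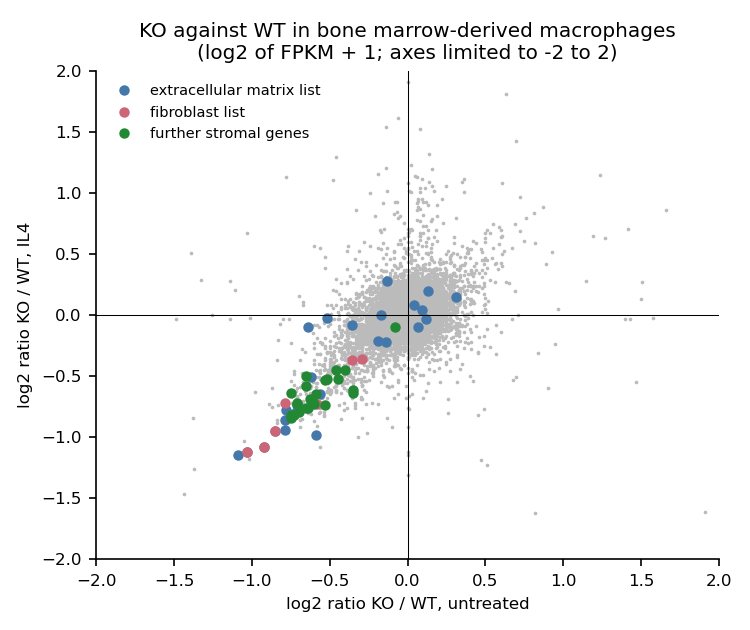
Log2 ratio of FPKM + 1 between the KO and the WT library of bone marrow-derived macrophages, untreated (x axis) and after IL-4 (y axis), 1 point per gene with both axes limited to -2 to 2. Fibroblast markers (red, list medians -0.79 and -0.73), further stromal genes (green, -0.62 and -0.67) and part of the matrix list (blue, -0.56 and -0.22) lie in the lower left.

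By library pair, 17 genes were at least 2-fold higher and 27 at least 2-fold lower in untreated KO bone marrow-derived macrophages (2 and 9 protein-coding), and 42 and 28 after IL-4 (23 and 10). They shared 3 higher genes, Snora43, Snord49b and the uncertain copy Tmem254c, and 11 lower genes, where unrelated lists would share 0.07 of each. Col3a1, Col6a1, Col6a2, Gdf3 and Timp3 were among the lower ones, besides Slc6a8, H3c13, the copy Tmem254b and 3 microRNA genes. Another 2 genes were higher untreated and lower after IL-4, and 4 the reverse. These opposite overlaps, for which no number for unrelated lists was computed, also lie above 0.07. Fibroblast markers had a median log2 ratio of -0.79 (-1.03 to -0.29) untreated and -0.73 (-1.12 to -0.36) after IL-4, the matrix list -0.56 (-0.72 to -0.14) and -0.22 (-0.79 to -0.03), and cholesterol synthesis genes -0.21 (-0.37 to -0.14) and -0.17 (-0.23 to -0.09). The chemokine gene Ccl8 was at 17.43 FPKM in untreated WT and 6.09 FPKM in untreated KO cells.

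After IL-4 type I interferon response genes were again higher in KO than in WT cells. Ifit2 was at 4.11 FPKM in WT and 14.67 FPKM in KO cells, Ifit3 at 5.79 and 18.72 FPKM, Isg15 at 10.31 and 31.71 FPKM and Oasl2 at 36.36 and 92.47 FPKM. The list had a median log2 ratio of 0.93 (0.80 to 1.12, percentile 100) after IL-4, with 13 of 28 at least 2-fold higher, against 0.03 (-0.05 to 0.08) in untreated cells. In WT cells these genes were lower after IL-4, with a median of -0.61 (-0.66 to -0.41) and Ifit3 going from 22.43 to 5.79 FPKM, while in KO cells they were higher, with 0.33 (0.26 to 0.45). The KO minus WT response was 0.91 (0.82 to 1.04), led by Ifit2 (1.68), Ifit3 (1.68) and Isg15 (1.45). MHC class I genes were higher in KO by 0.10 (0.03 to 0.16) untreated and 0.28 (0.14 to 0.32) after IL-4.

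The IL-4 targets themselves were slightly lower in KO cells after IL-4, with a median of -0.20 (-0.31 to -0.08), and at -0.02 in untreated cells. Their response in KO minus that in WT had a median of -0.13 (-0.17 to 0.04), with 11 of 30 above 0. Among all 125 genes induced at least 2-fold by IL-4 the median was -0.104 (-0.14 to 0.00), and among the 32 repressed genes 0.083 (-0.02 to 0.19). In all 45 genes had a KO minus WT response at least 2-fold above and 30 at least 2-fold below; the IL-4-induced genes Il4i1 (-0.94) and Retnla (-0.92) came close to the latter. No test of these differences was possible with 1 library per group.

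Over the 4 KO and WT pairs of both cell types, Slc6a8 was the 1 gene called among 10073, with a mean log2 ratio of -5.56 (SE 0.24, limma adjusted p = 0.0016) and lower in 4 of 4 pairs. No gene was called higher, with 845 genes in either direction at an unadjusted p under 0.05; the next gene by p, Vwf, had 0.57 (adjusted p = 0.176) and was higher in 4 of 4 pairs. At least 1.5-fold lower in all 4 pairs were Slc6a8, Arg1 and the lectin receptor gene Clec4a1, which the limma fit left at an adjusted p of 0.364 and 0.203. Arg1 was at 0.63 and 3.43 FPKM in untreated and IFN-gamma-treated WT peritoneal macrophages and at 0.06 and 0.49 FPKM in KO cells. Clec4a1 was at 6.14 and 3.6 FPKM against 2.95 and 0.58 FPKM there, and at 39.81 and 54.21 FPKM against 21.33 and 31.8 FPKM in bone marrow-derived macrophages. Without the IFN-gamma pair the limma count was 2.

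Markers of other cells were present at differing levels. Fibroblast markers were found in all libraries, with Col1a1 at 18.6 to 32.91 FPKM in peritoneal and 93.66 to 208.73 FPKM in bone marrow-derived macrophages. In peritoneal macrophages Cd22 was at 28.37 to 36.92 FPKM and Cd28 at 0.13 to 23.97 FPKM, while Cd79a, a B cell gene, was at 1.58 to 3.14 FPKM and the T cell gene Lck at 0.49 to 6.24 FPKM, with 6.24 in the KO IFN-gamma library. In that library Cd3e, Cd2, Cd5 and Zap70 were at 0 FPKM, while Cd3d and Cd8b1 were at 3.2 and 2.24 FPKM, so the T cell genes did not move together. Cd28 went from 19.45 to 0.56 FPKM with IFN-gamma in WT and from 23.97 to 0.13 FPKM in KO cells. The hemoglobin gene Hba-a1 was at 25.26 to 46.2 FPKM and, with Hba-a2, is an uncertain near-identical copy. With IFN-gamma edgeR called, with counts adjusted over the list alone in parentheses, 8 up (8) and 4 down (5) of 21 macrophage identity genes, C1qa and Cd14 among them, 5 up (6) and 2 down (2) of 13 resident macrophage genes, 3 up (3) and 1 down (2) of 10 monocyte genes, 3 up (3) and 1 down (1) of 5 T and NK cell genes, 2 up (3) and 1 down (1) of 4 neutrophil genes, 1 of 5 eosinophil, basophil and mast cell genes up (2), 5 of 7 dendritic cell genes up (5), 5 of 11 fibroblast genes down (7) and 3 of 8 erythroid genes up (4). B cell, sex-linked and ribosomal lists (45 genes) had 0 calls by edgeR, DESeq2 and limma and 0 at an unadjusted p under 0.05. X chromosome neighbours of Slc6a8 had 6 of 26 down (6) and reference genes 5 up (7) and 2 down (2) of 14. No mitochondrially encoded transcript was measured in either cell type.

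In bone marrow-derived macrophages, with IL-4, 10 macrophage identity genes rose (11 adjusted over the list alone) and 8 fell (8) of 21, with Cx3cr1 and Cd14 among the latter. Called with IL-4 were also 1 of 9 resident macrophage genes down (1 adjusted over the list alone), 3 up (3) and 2 down (3) of 10 monocyte genes, 1 of 4 T and NK genes down (1), 1 up (1) and 1 down (1) of 6 neutrophil genes, 2 of 4 eosinophil, basophil and mast cell genes up (2), 2 of 7 dendritic cell genes up (4) and 2 of 8 fibroblast genes down (2). X chromosome neighbours had 3 up (2) and 1 of 27 down, ribosomal genes 5 of 35 up (4), and reference genes 4 of 14 up (5, and 1 down). The B cell, erythroid and sex-linked lists (10 genes) had 0 calls by edgeR, DESeq2 and limma and 1 gene at an unadjusted p under 0.05, a B cell gene that is lower when adjusted over the list alone. For genotype, counted the same way, 1 up (2) and 2 down (5) of 9 resident macrophage genes, 4 of 10 monocyte genes down (4, and 1 up), 1 of 3 B cell genes down (1), 1 up (1) and 1 down (1) of 4 T and NK genes and of 4 eosinophil, basophil and mast cell genes, 1 of 3 erythroid genes down (3), L1cam among 27 X neighbours up (1), and 1 up (1) and 1 down (1) of 14 reference genes were called.

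**Figure D5:**
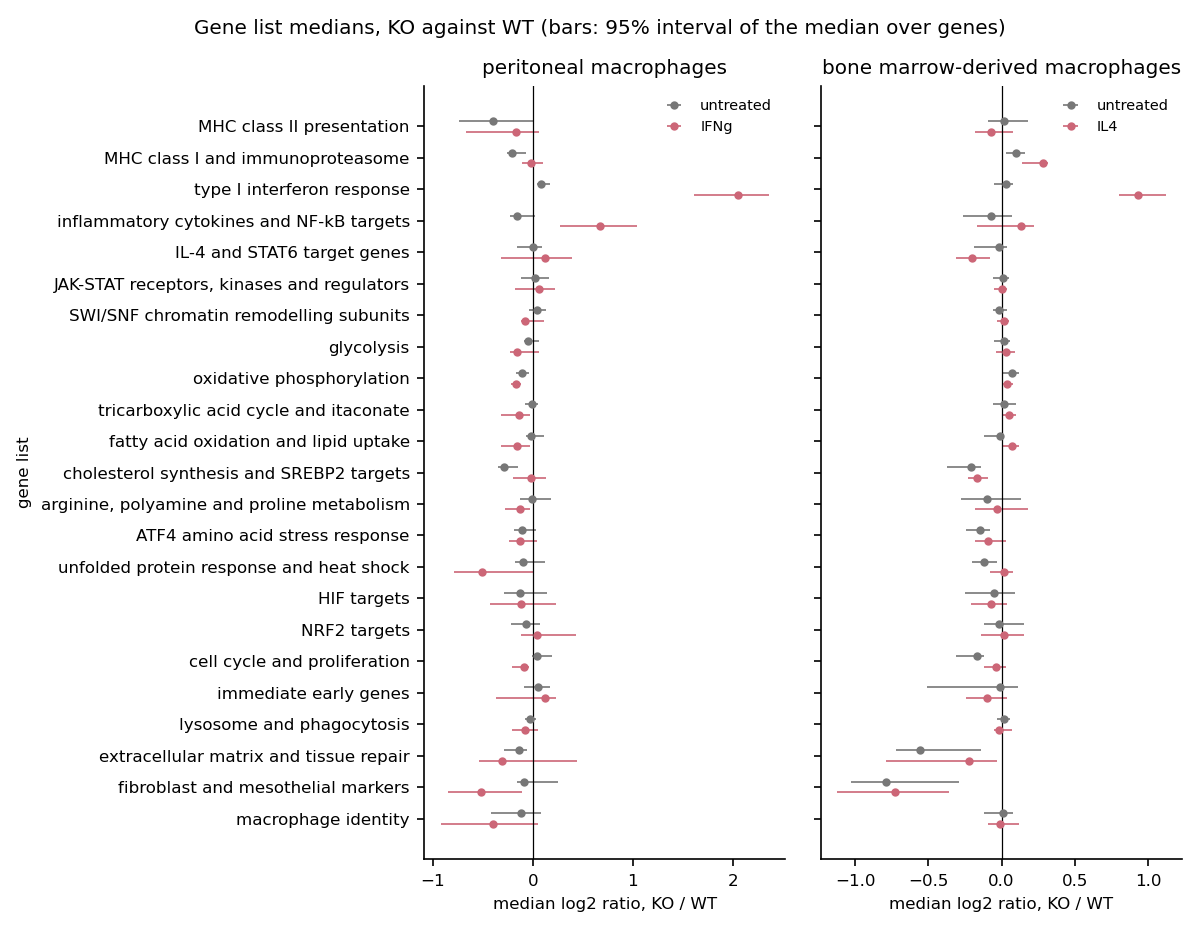
Median log2 ratio of KO against WT (x axis, log2 of FPKM + 1) for functional gene lists and for fibroblast and macrophage identity markers (y axis), untreated in grey and after the cytokine in red, in peritoneal (left) and bone marrow-derived macrophages (right), with bars for the 95% interval of the median over genes. The type I interferon list stands out after the cytokine, at 2.05 and 0.93, and the fibroblast list lies at -0.79 and -0.73 in bone marrow-derived macrophages.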

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

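All tests of the type I interferon pattern in this part were chosen after its result was seen. 3 results stood out because groups moved in opposite directions, and none of these differences was tested.

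Type I interferon response genes moved apart with IL-4 in bone marrow-derived macrophages: the list had a median log2 response of -0.61 in WT and 0.33 in KO cells. After either cytokine the list was higher in KO than in WT cells, while untreated cells of the genotypes were close. The KO minus WT response over all genes had a median of -0.063 in peritoneal and 0.014 in bone marrow-derived macrophages, which argues against scaling of the libraries. Among the 7 and 24 members with a mean of at least 5 FPKM in the untreated libraries the median was 1.24 (0.36 to 2.21) and 0.91 (0.72 to 1.04), which argues against low counts, and a larger response of all induced genes is argued against by percentile 100 among random lists matched on mean response in peritoneal macrophages and by the median of -0.104 (-0.14 to 0.00) over the genes induced by IL-4. An event in 1 culture of either genotype, such as interferon made in 1 dish, cannot be told apart from the genotype, because there is 1 library per group. Further, independent cultures of both genotypes would be needed.

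MHC class I and immunoproteasome genes had a median KO against WT log2 ratio of -0.21 in untreated peritoneal and 0.1 in untreated bone marrow-derived macrophages. Random lists matched on expression had medians of -0.05 and 0.02. In the untreated peritoneal pair the ribosomal list was at -0.21 as well, so the value is not particular to MHC class I genes. After IFN-gamma the MHC class I median was -0.02. Sex-linked genes in bone marrow-derived macrophages had a median KO against WT log2 ratio of -0.11 in untreated cells and 0.14 after IL-4, over 4 measured members.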

How the results depend on the processing

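Of 5614 values under alternatives 4871 kept their direction and their side of the threshold or stayed close, 7 kept their direction and lost their call, 736 moved and 0 reversed. Counts of genes could not be labelled reversed, a library-pair ratio only where it was at least 2-fold, and a median only where its interval left out 0. The balance of higher and lower genes did turn in places. In PM, KO against WT stimulated went from 166/95 to 432/475 with a 1.5-fold limit, and the KO minus WT response from 161/89 to 438/475. The limma additive fit and the restriction to protein-coding genes were chosen after seeing the data. Of the gene list medians 581 of 591 stayed close. The 7 lost calls, which concern the genes named from the fits, were Cxcl9, Nos2, Ifit2 and Slc6a8 for genotype in peritoneal macrophages with limma, Nos2 and Ifit2 there with protein-coding genes only, and Tmem254c in bone marrow-derived macrophages with DESeq2. Calls by list were lost as well, such as those of 9 tricarboxylic acid cycle genes that rose with IL-4, of which DESeq2 called 0 and limma 4, and of 3 erythroid genes that rose with IFN-gamma, of which DESeq2 called 0. Counts below are higher and lower genes, in the order WT response, KO response, KO against WT untreated, KO against WT stimulated and KO minus WT response, for peritoneal (PM) and then bone marrow-derived macrophages (BMDM). Counts between libraries change by construction with the fold limit, and with the pseudocount, which pulls the ratio of 2 libraries toward 0 when it is larger. They also do so with an expression filter or the restriction to protein-coding genes, which add or remove genes. For the other changes, those of the edgeR counts included, the cause was not tested. With a 1.5-fold limit they were 1175/1166, 1262/1676, 126/144, 432/475 and 438/475 in PM and 329/233, 343/180, 54/139, 131/181 and 141/84 in BMDM. With a pseudocount of 5, PM had 392/247, 350 lower in KO, 12/15, 78/31 and 85/31, and BMDM 71/9, 59/9, 3/4, 10/4 and 10/6. With a pseudocount of 0.1, PM had 90/80 untreated, 210 lower stimulated and 227 lower in the difference, and BMDM 92 lower in WT, 64 lower in KO, 29/48, 64/70 and 81/58; the median of type I interferon genes in untreated PM was 0.17 and that of repressed genes -0.325. With a mean of at least 5 FPKM, PM had 12/12, 97/55 and 89/43 in the last 3 comparisons and BMDM 89/26, 85/18, 4/8, 20/10 and 13/7. With no expression filter, PM had 62/73 untreated and 148 lower in the difference, and BMDM 92 lower in WT, 75 lower in KO, 54/70, 80/53 and 113/82. With protein-coding genes only, PM had 16/14 untreated and 55 lower in the difference, and BMDM 29 lower in WT, 24 lower in KO, 2/9, 23/10 and 18/6. DESeq2 called 1272/877 with IFN-gamma and 19/21 for genotype in PM, and 672/416 with IL-4 and 44/126 for genotype in BMDM. The limma fit called 0/0 for genotype in PM (1277 at an unadjusted p under 0.05), 997 higher with IL-4 and 63/182 for genotype in BMDM. DESeq2 size factors in edgeR gave 12/5 for genotype in PM, no filter on low counts 26/26 there and 527/726 for genotype in BMDM, and protein-coding genes only 1 higher for genotype in PM. Leaving out the IFN-gamma pair gave 2 lower genes over the pairs. With a 4-fold choice of responding genes the medians were 0.378 (induced) and -0.339 (repressed) in PM and -0.158 (induced) in BMDM, and with rescaling 0.336 and -0.207 in PM. Leaving a library out of an additive fit leaves 0 residual degrees of freedom and was not run. Depth in PM, with a median of 29 to 31 counts at about 1 FPKM, limits values of genes close to 1 FPKM.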

Other observations

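The test of further stromal genes was written before its result was seen; the tests of scaling and of the sign changes were chosen after.

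Matrix genes such as Col1a1 and Col6a1, lower in KO bone marrow-derived macrophages, are typical products of fibroblasts. A candidate explanation is fewer stromal cells in the KO cultures, which were grown in M-CSF with no sorting step given. A list of further stromal genes was trimmed to 25 after a first run because 5 of its genes had been seen before. The trimmed list had a median KO against WT log2 ratio of -0.62 untreated and -0.67 after IL-4. All 24 measured members were below 0 and 0 of them were on another list, which goes with that explanation. The 28 measured genes of the untrimmed list gave -0.63, with 28 below 0, and -0.70, with 27 below 0 and a highest value of 0.08. Abundant members of the trimmed list were Bgn, at 143.43 and 135.26 FPKM in WT and 91.58 and 79.59 FPKM in KO cells, Ccn2, at 70.62 and 62.27 against 46.59 and 39.34 FPKM, Aebp1, at 66.5 and 58.84 against 39.73 and 32.98 FPKM, and Igfbp7, at 55.12 and 60.08 against 43.11 and 38.18 FPKM. The median ratio of all genes was -0.004 and 0.009, which argues against scaling of the libraries, and whether macrophages or stromal cells made the transcripts is open.

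Peritoneal macrophages of the KO had larger responses to IFN-gamma among both induced and repressed genes. Rescaling left the medians of the KO minus WT response at 0.336 and -0.207, which argues against scaling. With 1 library per group, a difference between dishes or in the share of cells that responded stays open, and no biological explanation was tested.

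Over the 4 KO and WT pairs, the 8 possible sign changes are too few for a share under 0.05. The real signs called 1 gene, Slc6a8, and the highest other number was 0.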
